A study of Mus musculus with 6 samples.

How the data were processed

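Gene expression was measured in primary mouse astrocytes (strain C57BL/6, cerebral cortex of embryonic day 18, a purchased culture) on 6 one-colour Agilent Whole Mouse Genome arrays. Per the labels' protocols, cells were transfected 3 weeks after plating with a mixture of miR-29a, miR-29b and miR-29c precursors in the proportion 1 to 2 to 1, or with a negative control precursor, at 80 nM, and were harvested 48 h later. The protocol states a transfection efficiency above 90%. Each group holds 3 arrays, described as extraction replicates. Nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

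Per the file headers, the spot intensity was extracted with Agilent Feature Extraction 10.7.3.1 (version 10.7 in the submitters' processing notes), which subtracted the local background and gave a processed signal on a linear scale. The series value table deposited by the authors holds the same processed intensity, multiplied on each array by 1 constant factor that ranged from 2.627 to 3.427. It is linear and not centred, and the rule behind the factor is not given in the sources used here. Its medians were 149.3, 155.4 and 148.8 on the miR-29 arrays and 146.3, 164.8 and 162.2 on the control arrays, in the order of the replicates. There were 0 columns of other samples.

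The main values were the log2 of the processed signal (values under 1 set to 1) minus the 75th percentile of the array over its non-control probes. Control spots and outlier-flagged spots were left out, and spots of 1 probe were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 26428 of 41174 non-control probes. The files used here give accessions and no symbol, so probes were named by matching unversioned RefSeq accessions to the reference table for assembly GRCm38.p6, of which no coordinates were used because the array design is on another build. Of all probes, 26933 matched 1 gene and 14241 matched none. A gene was represented by its kept probe with the highest mean over the 6 arrays, and an unmatched accession was kept as its own transcript. This gave 19741 tested genes and transcripts, 13719 of them with a symbol.

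The miR-29 arrays were compared with the control arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2 scale, miR-29 minus control, with standard errors (SE) from this fit. For a gene that was not well above background on any array of 1 group, the fold is a bound. It sets the mean of the brighter group against, per array, the higher of the probe's own value and the lowest signal among probes well above background. Where the probe's own value is the higher on each array, the bound equals the measured fold. The number of arrays limits the precision.

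Before the data were examined, 24 gene lists were fixed from textbook knowledge, among them markers of other brain cell types. They were tested with camera, which compares a list with all other genes, at a correlation between genes of 0.01 and adjusted over the lists. The test was repeated with an estimated correlation and with fry, which does not compare a list with other genes. Missing values of 4 genes were filled with the gene's mean for these set tests. The genes named are the 12 with the largest fall and the 12 with the largest rise among genes past the threshold whose groups did not overlap and that have a proper symbol, up to 4 members past the threshold from each list, and 17 genes fixed in advance. The ranking of the 12 was restricted to genes above background on at least 1 array of both groups, which the fixed rule did not state. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here. A planned test of seed matches in 3' untranslated regions was not run, since such sequences are not used here.

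The procedure was tested on simulated data for this comparison with 200 changed genes among 19741. It recovered 97.1%, 76.5% and 63.6% of the genes lowered by 2, 1 and 0.5 on the log2 scale, and 93.9%, 75.8% and 45.5% of those raised by the same amounts. Of the 19541 unchanged genes 12 were called, 7.36% of the calls. Of 200 simulated lists 1 was shifted, and 0 of the others were called. The real comparison called 4493 genes lower and 6973 higher, so these rates describe a setting with far fewer changes. Noise was drawn separately for each gene, so the simulation could not test the correlation between genes set in camera.

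The alternatives tried were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited table, no filter and a stricter filter on dim probes, another variance model, the mean of all probes, the slide or the replicate number as a block, each array left out in turn, stricter tests, and other set tests. Normexp used the median spot signal, since the mean signal is not used here. Added after the data were seen were slide 1 alone, genes with a symbol alone, and scaling to the spike-in RNAs. The spike-in scaling was first made with the median of all 320 spike-in spots. After its counts were seen it was made again with the 6 of 10 spike-in types that were well above background, and both versions are reported.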

Results

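The data were 6 arrays of cultured mouse astrocytes, 3 after transfection with precursors of the miR-29 family of microRNAs and 3 after a negative control precursor. MicroRNAs are short RNAs that lower the level of messenger RNAs they pair with. The title of the series names miR-29 as a potential determinant of longevity, and the design asks which transcripts differ once it is raised in astrocytes. Between 62% and 66.8% of the probes were well above background on each array, the 75th percentile of the signal lay between 501 and 663, and 0 spots were saturated. Across genes, arrays of the same group correlated at 0.994 to 0.998 and arrays of different groups at 0.975 to 0.985. Slide 1 held the 3 miR-29 arrays and control replicate 1, and slide 2 held control replicates 2 and 3.

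Most collagen genes were lower in the miR-29 arrays: of 31 tested 24 fell, 3 rose and 4 did not pass, with a median log2 fold change of -0.83. Which cells of the cultures carried this fall was not tested. The 3 lists that hold them passed camera, and none did with an estimated correlation (adjusted p = 0.0586, 0.0642 and 0.165 with an estimated correlation). The estimates were -0.00379 for the type IV and basement membrane list, -0.0227 for the fibrillar list and 0.0571 for the other collagens. The estimates of the type IV and fibrillar lists lay below the correlation set in the main test. A higher correlation therefore does not account for their lost calls, and what does was not tested. Col3a1, a chain of type III collagen, fell by 3.55 on the log2 scale (SE 0.0975, adjusted p = 2.24e-05, n = 3 per group; -2.37 with its other probe), and the type I collagen gene Col1a2 fell by 2.27 (SE 0.0521). Col4a2, a basement membrane collagen, fell by 1.69 (SE 0.0453; -1.18 with its other probe), and Sparc, a collagen-binding glycoprotein, fell by 1.42 (SE 0.0757). Of 34 cell cycle genes 29 fell, 1 rose and 4 did not pass (camera adjusted p = 1.64e-10; adjusted p = 0.165 with an estimated correlation). The astrocyte glutamate transporter gene Slc1a3 rose by 1.68 (SE 0.0874, adjusted p = 6.09e-05). Of the 19741 genes and transcripts tested, 4493 were lower and 6973 higher (60.8% of those past the threshold), and 8275 were not past it. At least 2-fold changes were found in 718 lower and 650 higher genes, of which 47 and 125 have only a bound in 1 group.

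The split between lower and higher genes depended on the scaling. With the arrays scaled to the 6 detected spike-in types, 7438 genes were lower and 3033 higher (29% higher), and with all spike-in spots 8352 were lower and 2778 higher (25% higher). Scaling to the detected types moved the median of all genes by -0.245, from 0.0679 to -0.178, and turned the sign of 964 genes called higher. Of the 1368 genes with a 2-fold change, 1349 kept their call and direction with the detected types.

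Of 10 fibrillar collagen genes, 9 fell and 1 did not pass the test, with a median log2 fold change of -1.67 (camera adjusted p = 8.58e-07; adjusted p = 0.0642 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher. Col2a1, the main collagen of cartilage, fell by 3.94 (SE 0.384), and by 3.03 against the control array on the same slide, while its other probe gave -1.16. Col5a2 fell by 2.17 (SE 0.0456). The probes of Col1a1 differed in size: the brightest gave -1.28 (SE 0.0711), and the other probes gave -3.25 and -3.93. In the type IV collagen and basement membrane list 17 of 20 genes fell and 3 did not pass, with a median of -0.71 (adjusted p = 3.7e-09; adjusted p = 0.0586 with an estimated correlation). The counts were again 17 and 0 adjusted over the list alone. Col4a1 fell by 0.77 with its brightest probe and by 1.84 with the other. Col15a1 fell by 1.11 and Nid1, a linker of laminin and type IV collagen, by 1.10. Of 14 other collagen genes 9 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone. Their median was -0.64 (adjusted p = 0.00811; adjusted p = 0.165 with an estimated correlation), and the list lost its call when scaled to all spike-in spots (-0.9039, adjusted p = 0.0501). Col6a1 fell by 1.22 and Col9a1 by 1.00. Col17a1, not well above background in the control arrays, was 2.04-fold higher, where the bound equals the measured fold and is not a cautious lower limit. Its call was lost with normexp background correction (0.22, adjusted p = 0.0868).

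**Figure D1:**
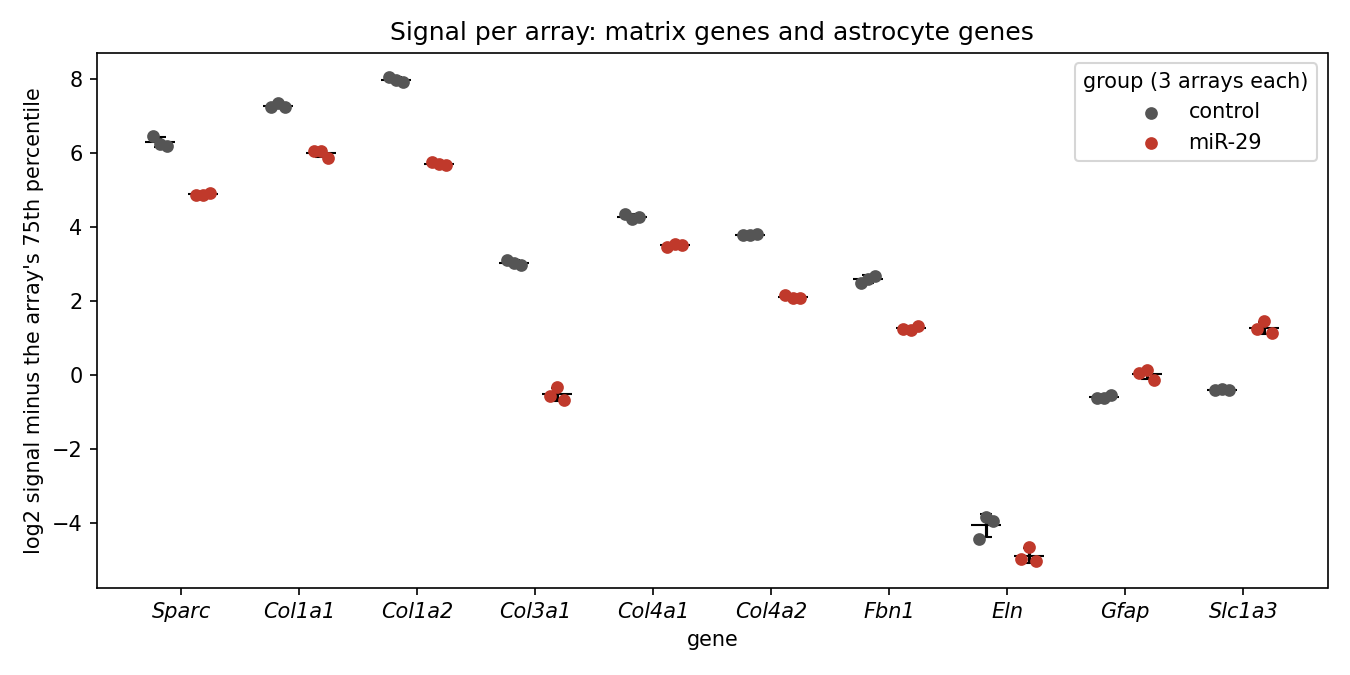
Log2 signal minus the array's 75th percentile (vertical axis) of 10 genes (horizontal axis) on the 3 control and 3 miR-29 arrays; points are arrays, horizontal marks are group means and bars are 1 SD. The 3 miR-29 arrays lie below the 3 control arrays for the 8 matrix genes and above them for Gfap and Slc1a3; with spike-in scaling these directions were kept.

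Genes that process collagen followed the same direction. Of 23 genes for collagen processing and cross-linking 17 fell, 2 rose and 4 did not pass, also when adjusted over the list alone, with a median of -0.36 (adjusted p = 1.31e-05; adjusted p = 0.153 with an estimated correlation). The lysyl oxidase family member Loxl2 fell by 2.91 (SE 0.129; -1.29 with its other probe), the collagen chaperone gene Serpinh1 by 1.34 and the prolyl hydroxylase gene P3h1 by 1.25. Adamts3, a procollagen protease gene, was not well above background in the miR-29 arrays and was at least 2.77-fold lower. Of 22 integrins and matrix receptors 14 fell, 0 rose and 8 did not pass, with 14 lower adjusted over the list alone. Their median was -0.50 (adjusted p = 1.38e-06; adjusted p = 0.157 with an estimated correlation). The integrin genes Itgb3, Itga6 and Itga5 had log2 fold changes of -2.38, -2.17 and -1.705, and the dystroglycan gene Dag1 fell by 1.61.

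The remaining matrix lists were not past the camera test, although fry called both lower (adjusted p = 0.000467 and 7.16e-05). Among 26 genes of elastic fibres, microfibrils and matrix glycoproteins 11 fell and 7 rose (11 and 8 adjusted over the list alone), with a median of -0.18 and adjusted p = 0.153. With spike-in scaling 15 were lower and 2 higher, with a median of -0.42. Fbn1, the main microfibril component, fell by 1.32 (SE 0.0683), Mfap2 by 1.05 and Mfap5 by 1.47, the last above background on 1 of the 3 miR-29 arrays, and Mfap4 rose by 1.34. Eln, the gene of elastin, fell by 0.82 (SE 0.182, adjusted p = 0.00998), a call lost with the slide as a block (-0.46, adjusted p = 0.0669) and with normexp (-0.20, adjusted p = 0.103). Of 21 matrix proteases and inhibitors 8 fell and 6 rose, with the same counts adjusted over the list alone and adjusted p = 0.131, and 11 were lower and 5 higher with spike-in scaling. The list passed the test with the slide as a block (adjusted p = 0.0309). The gelatinase gene Mmp2 fell by 2.63 (SE 0.0475), and Mmp15, Adam12 and Adam19 fell by 1.58, 1.51 and 1.38.

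Of 48 miR-29 targets described in other systems, 34 fell, 4 rose and 10 did not pass, also when adjusted over the list alone. The median was -0.56 (adjusted p = 3.7e-09; adjusted p = 0.117 with an estimated correlation), and 28 members of the written list are also in other lists, the collagen genes among them. At least 2-fold changes were found in 14 lower targets and 1 higher target. The higher one was Igf1, which rose by 1.66 (SE 0.061, adjusted p = 3.38e-05, and 0.73 with its other probe). The lipase gene Lpl fell by 0.95 (SE 0.0508), the apoptosis regulator gene Mcl1 by 0.43 with its brightest probe and 1.22 with the other, and the secretase gene Bace1 by 0.28 (SE 0.0531, adjusted p = 0.00515). The DNA methyltransferase gene Dnmt3a had a log2 fold change of 0.081 (SE 0.0814, adjusted p = 0.418), and its other probes gave 0.15 (adjusted p = 0.179) and -0.60 (adjusted p = 0.000427). Dnmt3b had 0.17 (SE 0.149, adjusted p = 0.345). In the DNA methylation and demethylation list 8 of 15 genes fell, 2 rose and 5 did not pass, also when adjusted over the list alone. The median was -0.19 (-0.44 with spike-in scaling, where 10 were lower and 0 higher). The camera adjusted p = 0.0454 of this list rested close to the threshold. It was 0.165 with an estimated correlation, 0.215 without genes held by several lists, 0.0503 without miR-29 replicate 1 and 0.0949 without control replicate 1. The thymine glycosylase gene Tdg fell by 1.44, the maintenance methyltransferase gene Dnmt1 by 0.60, and Tet3 by 0.75, where the other probe gave -0.766 and did not pass (SE 0.344, adjusted p = 0.1).

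Genes of the S, G2 and M phases of the cell cycle fell. Of 34 tested 29 were lower, 1 higher and 4 not past the test, with the same counts adjusted over the list alone, and their median was -0.80 (adjusted p = 1.64e-10; adjusted p = 0.165 with an estimated correlation). The cyclin genes Ccna2 and Ccne2 fell by 1.86 and 1.54, the replication licensing gene Cdc6 by 1.79 (-1.10 with its other probe) and the mitotic kinase gene Aurkb by 1.77. Against the control array of slide 1 the median of the list was -0.84. Of 30 p53 targets and senescence-associated genes 14 fell and 9 rose (14 and 10 adjusted over the list alone), with a median of -0.061 and adjusted p = 0.231 (0.00914 and lower with fry), and 17 were lower and 5 higher with spike-in scaling. The insulin-like growth factor binding protein gene Igfbp5 rose by 2.16 and the pro-apoptotic gene Pmaip1 by 1.64, and Btg2 and Zmat3 fell by 1.25 and 1.09, with -0.41 and -0.55 for the other probes of Btg2.

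Endoplasmic reticulum stress genes were lower in 17 of 24 cases, higher in 1 and not past the test in 6, also when adjusted over the list alone. The median was -0.46 (adjusted p = 2.81e-06; adjusted p = 0.157 with an estimated correlation). Sdf2l1 fell by 1.52, Edem1 by 1.38 (-0.36 and -0.85 with its other probes), Herpud1 by 1.15 and the chaperone gene Hspa5 by 0.94. Of 25 genes of TGF-beta, PDGF and CCN signalling 16 fell and 3 rose (17 and 4 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.000262; adjusted p = 0.157 with an estimated correlation). Ccn3, Pdgfc and Ccn2 fell by 1.66, 0.98 and 0.97, and the receptor gene Tgfbr1 rose by 1.21 (0.61 with its other probe).

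Markers of astrocytes went both ways. Of 21 tested 10 rose, 4 fell and 7 did not pass, also when adjusted over the list alone, with a median of 0.29 (adjusted p = 0.159; 0.00171 and higher with fry) that was 0.043 with spike-in scaling, where 5 were higher and 4 lower. Beside Slc1a3, the fatty acid binding protein gene Fabp7 rose by 1.31 (SE 0.0436), Aldh1l1 by 0.74 and the filament gene Gfap by 0.62 (SE 0.0771). The glutamate transporter gene Slc1a2 had 0.29 (SE 0.107, adjusted p = 0.0596), while its other 3 probes rose by 0.35 to 0.48. It passed with the slide as a block (0.44, adjusted p = 0.0443), with normexp (adjusted p = 0.0379), with median centring (adjusted p = 0.027) and without miR-29 replicate 3 or control replicate 2 (adjusted p = 0.0379 and 0.0482). The water channel gene Aqp4 had 0.16 (SE 0.121, adjusted p = 0.29). Of 24 reactive astrocyte genes 13 fell, 6 rose and 5 did not pass, also when adjusted over the list alone, with a median of -0.24 (adjusted p = 0.00811; adjusted p = 0.165 with an estimated correlation). With spike-in scaling 15 were lower and 1 higher, with a median of -0.49. Emp1 and S1pr3 fell by 1.35 and 1.04, the complement gene C3 by 0.79 and Ptx3 by 0.68.

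No list of another cell type passed the camera test. Fry called the fibroblast list higher (adjusted p = 0.00236) and the endothelial and oligodendrocyte lists lower (adjusted p = 0.00171 and 0.0352). Of 17 fibroblast, meningeal and mural cell markers 11 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.157). The median turned to -0.044 with spike-in scaling, where 7 were higher and 4 lower. The smooth muscle genes Myh11 and Cnn1 rose by 1.61 and 1.34 and Aldh1a2 by 0.81, and S100a4 fell by 1.21. Of 5 tested microglia markers 2 fell and 1 rose, also when adjusted over the list alone (median -0.35, adjusted p = 0.227). Their median was 0.033 against the control array of slide 1, and with spike-in scaling 4 were lower and 0 higher. The fall of Csf1r by 1.39 was lost with the slide as a block (adjusted p = 0.178) and was opposed by another probe (0.37). The rise of P2ry12 by 0.53 was lost without miR-29 replicate 1, miR-29 replicate 2 or control replicate 2 (0.55, 0.42 and 0.57, with adjusted p = 0.0688, 0.0898 and 0.0552). It was also lost with spike-in scaling and with normexp, where it was 0.097 (adjusted p = 0.376). Csf1r also lost its call without any single array other than miR-29 replicate 2 or control replicate 1 (adjusted p = 0.0516 to 0.0636), although its log2 fold change stayed between -1.411 and -1.121. Of 11 oligodendrocyte lineage markers 3 fell and 5 rose (4 and 5 adjusted over the list alone; median -0.23, adjusted p = 0.752), with falls of Cspg4 (-1.715, and -1.07 with its other probe) and Cldn11 (-1.486) and a rise of Olig2 by 1.35. Their median was 0.33 against the control array of slide 1. Of 15 neuron markers 6 fell and 5 rose, also when adjusted over the list alone (median -0.098, and 0.040 within slide 1; adjusted p = 0.452), with rises of Elavl3 by 1.67 and Elavl4 by 1.39 and a fall of Gad2 by 0.95 that another probe did not show (-0.0287). Of 9 endothelial markers 3 fell and 3 rose (4 and 3 adjusted over the list alone; median -0.029, and 0.109 within slide 1; adjusted p = 0.434), among them Slco1a4, which fell by 1.12, Flt1, which fell by 0.35, and Vwf, which rose by 0.84 (0.463 within slide 1) and did not pass with normexp (adjusted p = 0.101).

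The other lists were not past the camera test, although fry, which asks whether the genes of a list move on balance one way, called the insulin list (adjusted p = 0.00102) and the small-RNA list (adjusted p = 0.000786) higher. Of 31 interferon-stimulated genes 15 rose and 7 fell, also when adjusted over the list alone (median 0.28, adjusted p = 0.694), but with spike-in scaling 6 were higher and 13 lower (median 0.030). Psmb9 and Isg15 rose by 1.10 and 0.88, and Tap1 and Oas2 fell by 1.73 and 1.51. Of 28 insulin, IGF and longevity-linked genes 12 rose and 6 fell, also when adjusted over the list alone (median 0.13, adjusted p = 0.245), but with spike-in scaling 5 were higher and 8 lower (median -0.11). The growth factor genes Igf1 and Igf2 rose by 1.66 (0.73 with its other probe) and 0.65. The receptor gene Igf1r rose by 0.61 (0.40 within slide 1), where 1 of its other probes did not pass (0.105). Of 25 cholesterol biosynthesis genes 9 rose and 7 fell, also when adjusted over the list alone, and the signs differed: median 0.033 (-0.21 with spike-in scaling, where 3 were higher and 12 lower, -0.0065 within slide 1 and -0.021 in the deposited table) and mean 0.057, but downward in camera (adjusted p = 0.752). Tm7sf2 and Idi1 rose by 1.00 and 0.96. Stard4 rose by 1.29, with other probes that did not pass (0.00269 and -0.0818), and lost its call with the slide as a block (0.84, adjusted p = 0.0524). Of 14 genes of the small-RNA machinery 5 rose and 1 fell, also when adjusted over the list alone (median 0.068, adjusted p = 0.452), but with spike-in scaling 1 was higher and 4 lower (median -0.18). Tnrc6b rose by 0.73, where 2 of its other 3 probes did not pass (-0.231 and 0.455). Drosha rose by 0.44 and Ago2 by 0.34, and neither passed with spike-in scaling. Ago2 also lost its call with the slide as a block (adjusted p = 0.0561), and another of its probes gave 0.099 (adjusted p = 0.277). Ago1 fell by 0.66 with its brightest probe and rose by 0.36 with another.

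**Figure D2:**
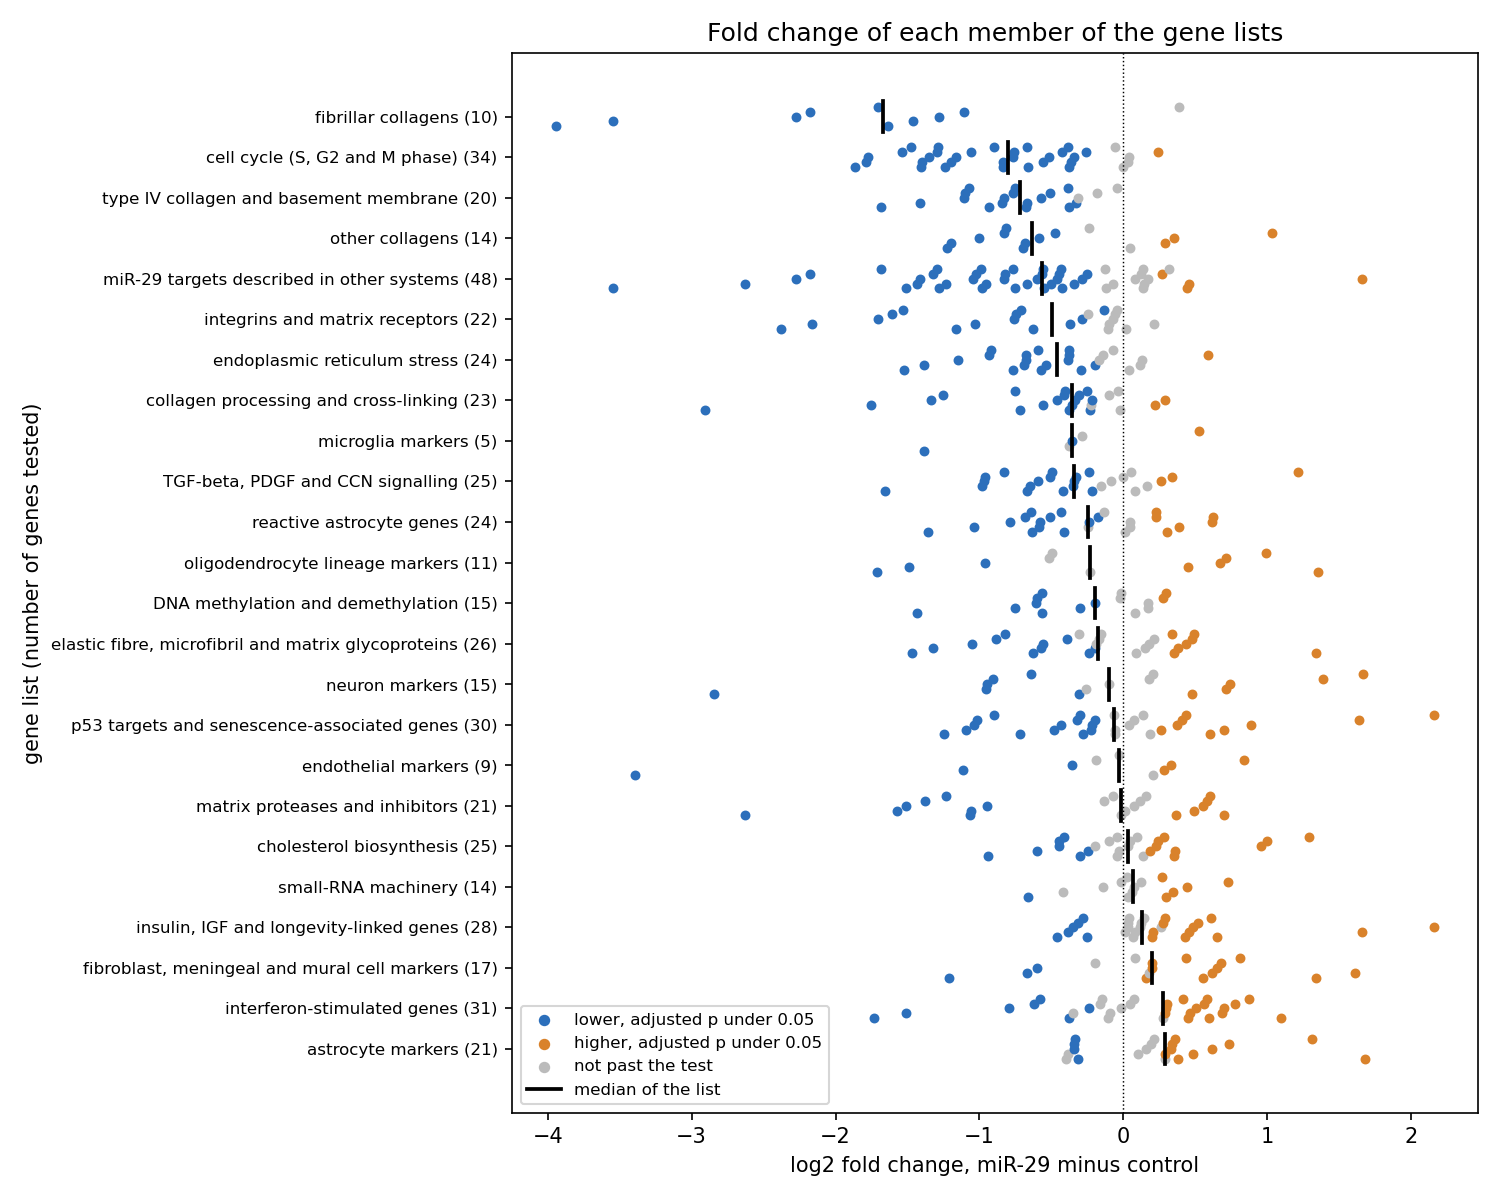
Log2 fold change, miR-29 minus control (horizontal axis), of each tested member of the 24 gene lists (vertical axis, number tested in brackets); blue and orange points passed the test as lower or higher, grey points did not, and black lines are list medians. The medians run from -1.67 for the fibrillar collagens to 0.29 for the astrocyte markers; spike-in scaling moves every point by -0.245 and turns the positive medians of the cholesterol, small-RNA, insulin and fibroblast lists negative.

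Beside Col2a1, Col3a1 and Loxl2, the 12 named genes with the largest fall held Ly6f (-3.81, and -2.702 within slide 1), Ly6c1 (-3.39) and Ly6a (-2.91), members of a family of related cell surface proteins. Their probes may also bind each other's transcripts, which was not tested, so each value is uncertain. Plxdc1 fell by 3.30, the potassium channel gene Kcnn4 by 2.85, the uracil glycosylase gene Ung by 2.81 and the matrix proteoglycan gene Prelp by 2.70 (-1.37 with its other probe). The vesicular glutamate transporter gene Slc17a7 fell by 2.85 (SE 0.873, adjusted p = 0.0326), was above background on 1 of 3 miR-29 arrays, and lost its call with the slide as a block (-1.47, adjusted p = 0.292) and without any single array other than miR-29 replicate 2 or control replicate 1 (adjusted p = 0.0581 to 0.0973). The largest rise was that of Cidea, a lipid droplet protein gene, by 2.57 (SE 0.152), followed by Zfp185 (2.44, and 1.45 with its other probe), Erich3 (2.29), Gprasp2 (2.27), Ccnjl (2.19), Igfbp5 and Spink2 (2.14). Wdr17 rose by 2.09, the decarboxylase gene Ddc by 2.04, Btbd17 by 2.03, the chloride transporter gene Slc12a5 by 1.97 and the receptor gene Notch3 by 1.95.

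Because the slides differed in the groups they held, the comparison was repeated with the slide as a block, where 3606 genes were lower and 5660 higher. Of the 1368 genes with a 2-fold change, 1225 passed with the slide as a block, and 1088 differed at least 2-fold within slide 1, a comparison that shares 4 of the 6 arrays with the main one and is not independent of it.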

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

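Slide 1 alone, both spike-in scalings and genes with a symbol alone were added after seeing the data (the limits for all spike-in spots before their counts were seen), and the detected spike-in types after the counts with all spots. Of the counts compared, 120 stayed within 1.5 times the main count and 16 did not. Genes at least 2-fold lower and higher were 353 and 143 with normexp, and 1029 were 2-fold higher with no filter on dim probes, which tests more genes. Normexp adds the offset of 50 to signals whose array medians, as processed, were 43.9 to 61.7, so it shrinks the folds of dim probes. Calls lost with normexp in dim genes are to be read with this limit. Beyond 1.2-fold, 2188 genes were lower and 2996 higher, a stricter test. With the detected spike-in types 7438 were lower, 3033 higher, 1346 2-fold lower and 294 2-fold higher, and with all spike-in spots 8352, 2778, 1453 and 272. Among genes with a symbol 424 were 2-fold higher, fewer being counted. Camera with an estimated correlation called 0 lists lower, and fry called 4 higher. Where not stated, the cause was not tested. Leaving out 1 array gave 3674 to 5736 lower, 5674 to 7423 higher, 660 to 919 2-fold lower and 558 to 730 2-fold higher genes, and 10 to 11 lists lower. The highest of each gene count came without control replicate 1, where group and slide cannot be told apart.

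Over all alternatives, named genes kept direction and call in 2190 cases, lost the call in 35, gained it in 8 and turned in 2. With the mean of all probes Ago1 was 0.01742 and Dnmt3a -0.1239, since their probes oppose each other. Lists kept theirs in 498 cases, lost it in 19 and gained it in 11. With a replicate block 4524 genes were lower and 6998 higher. Deviations of equally numbered arrays correlated at 0.13, 0.094 and 0.25, so the numbers are not taken to pair the samples, although every array correlated best with its own number, a hint from the data. Not run were the seed match tests, the scan day (1 day) and leaving out saturated spots (0 spots). Dim probes limit the folds: 47 lower and 125 higher 2-fold genes have only a bound.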

Other observations

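The tests of the fibroblast markers, of the other probes, of the slide, of the olfactory receptors, of the microglia markers and of chance were chosen after the results were seen. For the tests of single probes, of all spike-in spots and of dim probes among all genes the limits were written before their results were seen, although the spike-in scaling itself was added after the data had been looked at. The olfactory receptor family was taken up as a pattern only after the cell cycle genes had been tested, and both are given.

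Gene families, formed from shared symbol stems after the data were seen, showed other shifts. Of 87 families with at least 15 members, Cfap genes of cilia and flagella were higher in 15 of 19 cases (median 0.54, adjusted p = 0.00726), with a median of 0.29 under spike-in scaling, where 10 were higher and 2 lower. Mitochondrial ribosomal genes were higher in 33 of 49 cases for Mrpl and 21 of 29 for Mrps, with medians of 0.27 and 0.30 that were 0.020 and 0.058 with the detected spike-in types (11 higher and 8 lower, and 7 and 4), and the median of Mrpl was -0.0037 with all spike-in spots. Cytosolic Rpl genes were higher in 30 of 46 cases (median 0.21, which turned to -0.036 with spike-in scaling, where 3 were higher and 5 lower), while Rps genes, higher in 22 of 41 (median 0.24, turned to -0.0055, with 1 higher and 7 lower), did not pass as a family (adjusted p = 0.131). Ccdc, Taf and Polr genes were higher in 47 of 85, 15 of 20 and 14 of 26 cases, with medians of 0.26, 0.34 and 0.24 that were 0.013, 0.097 and -0.011 with the detected spike-in types and, for Ccdc, -0.011 with all spike-in spots. With the detected types 22 were higher and 14 lower for Ccdc, 6 and 3 for Taf, and 5 and 4 for Polr. Genes of the stem Ly were lower in 8 of 15 cases (median -0.67, -0.33 within slide 1, and 9 lower and 0 higher with spike-in scaling). With an estimated correlation none of these families passed (adjusted p = 0.836).

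The 44 collagen and basement membrane genes had a median log2 fold change of -0.79, for which an action of miR-29 itself stays open as an untested explanation. A lower share of fibroblast, meningeal or mural cells is argued against, in the main scaling, by the 14 markers of these cells that are in no matrix or target list: their median was 0.377 (95% interval -0.196 to 0.814). Single markers, named after their values were seen, went both ways (Acta2 0.62, Tagln 0.68, S100a4 -1.21). Scaling to the detected spike-in types moves each of these values by -0.245. The interval treats the markers as independent, although the estimated correlation in the full list of 17 was 0.141. A slide difference is argued against by the value within slide 1, a median of -0.774 (quartiles -1.26 and -0.286). Of the 17 genes with several probes 76.5% had every probe lower, between the limits set in advance, and the other probes of all 17 had a median of -0.817 (95% interval -1.42 to -0.0431), not wholly below the limit of -0.2. Among the 14 of them that fell, a restriction chosen after those values were seen, the other probes had a median of -1.02 (95% interval -1.84 to -0.293) and 13 had every probe lower, by sign alone, which argues against a faulty probe as the cause over this group, and leaves it open for Col11a1 and Col11a2, whose other probes showed no clear fall (0.12 and -0.0431), and for the 21 genes that fell with 1 probe.

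Olfactory receptor genes, dim on these arrays, were lower in 27 of 148 cases and higher in 1, with a median of -0.43 (59 lower, 1 higher and -0.67 with spike-in scaling). Of all 19741 tested, 4493 were lower and 6973 higher, and 7438 were lower with the detected spike-in types. The share of falls in this family was therefore no larger in the main scaling and similar with spike-in scaling. The family stood apart by its median and its lack of rises. A slide difference may account for the lower median: within slide 1 it was 0.089 (95% interval 0.0371 to 0.167), and 6 of the 27 stayed lower with the slide as a block. Background common to dim probes is argued against, since control replicate 1 lay below control replicates 2 and 3 by 0.695 more in this family than in genes of equal signal (-0.695, bootstrap 95% interval -0.747 to -0.6). What differed between the slides, or between these RNA extracts, stays open, because control replicate 1 is the only control array of slide 1.

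More genes were higher than lower in the main comparison. The 75th percentile scaling may produce this, as 25% of the called genes were higher with all spike-in spots and 29% with the detected types, shares that follow from the shift the spike-in RNAs set. All 6 detected types were higher in the miR-29 arrays relative to the 75th percentile, by 0.194 to 0.31, and by 0.187 on average within slide 1. Background in dim probes is argued against by the brightest of 3 equal groups of genes, in which 67.5% of the called genes were higher, but not for 2-fold changes, of which 168 were lower and 69 higher in that group against 267 and 393 in the dimmest. Whether the spike-in RNAs or the 75th percentile hold the truer level stays open.

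For the 34 cell cycle genes the median within slide 1 was -0.84 (quartiles -1.32 and -0.417), and the 5 microglia markers had a median of -0.354 (range -1.39 to 0.529), which was 0.0329 within slide 1.

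The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4493 lower, 6973 higher, 718 2-fold lower and 650 2-fold higher genes, and the highest count of any other split was 0 in each case (1 of the 10 splits gave as many). Each other split had miR-29 and control arrays on both sides, so the difference between the groups entered the spread. Low gene counts follow from that mixing and do not weigh chance. For lists the real split gave 11 lower and 0 higher. Counting either direction, since a split and its mirror are 1, the highest other was 10, a count of lists higher, and 1 of the 10 splits gave as many as 11, while 10 of 10 gave at least 0.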
